A study of Homo sapiens with 114 samples.

How the data were processed

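Per the submitters' processing notes, the arrays were summarized with GCRMA, all data sets being normalized together, and the deposited table holds 1 log2 value per probe set and array. These log2 values were used as they stood, since probe-level data were not used here. The table holds 54675 probe sets, of which 41091 carry 1 gene symbol, 1801 carry several, 11721 carry none and 62 are array controls. Each of the 19775 genes was represented by its probe set with the highest mean over all arrays.

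Groups were compared with limma 3.58.1 in R 4.3.3, by linear models of group means followed by empirical Bayes moderation. One model was fitted per control family, meaning the compounds whose labels name the same control cultures, at both times, with those controls. The 6 families were CsA, Aa, Nnm with Kbr, Ota, Fk with Ra, and CdCl with Di. A gene was tested in a family when its log2 value exceeded 4 on at least 3 of the family's arrays, which left 10806, 11106, 11036, 11138, 10889 and 11045 genes in that order. A gene was called when its Benjamini-Hochberg adjusted p over all genes of the comparison was under 0.05, and the number of calls of at least 2-fold is given beside each total. The comparisons, this threshold, the filter, the gene lists and the alternatives were chosen before the data were examined, except where the text says otherwise.

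Each of 23 gene lists, 534 genes in all with 48 of them not in the table, was tested with limma's camera at its preset correlation of 0.01 between genes when at least 5 members were tested. The same test with a correlation estimated from the arrays is given beside it, and p was adjusted over the lists of a comparison. A named list whose call was lost in that second test is given with its p there. List members were counted over all genes and also adjusted over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

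The genes named follow a rule. For each main comparison, the 5 called genes with the largest rise and the 5 with the largest fall were eligible among those whose 3 treated arrays all lay outside the range of the 3 control arrays. For each list past its test the 3 called members with the largest change were eligible, and for other lists with at least 2 called members the 2 largest. The other doses and times repeated these genes and added the 2 largest called genes each way. The dose, time and direct comparisons took 3 each way, and the genes shared by compounds were the 10 called in most main comparisons in 1 direction. Probe sets with several symbols were not named. Some genes of comparisons with at most 5 calls were named outside this rule, and the text says so.

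The replicate numbers of the labels were checked as possible pairs of cultures, by correlating the residuals of treated and control arrays with the same number. The numbers were taken to pair the samples where every pair's correlation exceeded 0.1. This held for CsA (lowest, median and highest r 0.534, 0.799 and 0.931 over 6 pairs), Aa (0.28, 0.428 and 0.537 over 12) and Nnm with Kbr (0.139, 0.401 and 0.673 over 24). It did not hold for Ota (−0.0542, 0.194 and 0.409), Fk with Ra (−0.176, 0.202 and 0.76) or CdCl with Di (−0.274, −0.0485 and 0.16), over 12 pairs each. In the first 3 families a fit with the replicate number as a block is given beside results it moved.

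Other alternatives, tried 1 at a time, were no filter, a filter at log2 6, the mean of all probe sets of a gene, leaving out probe sets with the suffixes _x_at and _s_at, quantile normalization, the trend option of limma, a fit of all arrays at once, a fit of only the arrays of a comparison, and leaving out each array in turn. Similarity of the 26 responses was taken from average linkage clustering on 1 minus Pearson r over 8021 genes, divided in 3 clusters, with complete linkage and Spearman correlation as alternatives. No array was left out of the values in the results.

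The procedure was tested on simulated data in which 67, 67 and 66 genes were shifted by 0.5, 1 and 2 log2 units. In that order it recovered 1.49%, 44.8% and 80.3% of them in CsA 48 h, and 19.4%, 67.2% and 98.5% in Aa high 48 h. In Kbr high 48 h these shares were 17.9%, 59.7% and 95.5%, and in Nnm high 48 h 16.4%, 64.2% and 93.9%. In Ota high 72 h they were 7.46%, 70.1% and 84.8%. In Fk 48 h they were 1.49%, 40.3% and 89.4%, and in Ra 48 h 4.48%, 44.8% and 81.8%. In both CdCl 48 h and Di 48 h they were 47.8% and 82.1%, and 100% and 98.5% for the largest shift. Unshifted genes made up 2.7% to 7.94% of the calls, and without any shift there were 0 calls except 1 in Nnm high 48 h. These values need not hold for the real arrays, where a split of the Nnm doses gave 1580 genes.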

Results

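RNA from HK-2 cells, an immortalized human renal proximal tubular epithelial line, was measured on Affymetrix arrays to describe how 9 compounds change gene expression. The arrays fell into 38 groups of 3 replicate cultures, of which 26 were treated and 12 were vehicle controls. The compounds appear under the abbreviations of the labels, and doses only as high or low. Aa, Nnm and Kbr were given at a high and a low dose for 24 and 48 h, and Ota at a high and a low dose for 24 and 72 h. CsA, Fk, Ra, CdCl and Di were given at 1 dose for 12 and 48 h. Nnm and Kbr shared their control cultures, as did Fk with Ra and CdCl with Di.

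Changes are given in log2 units ± standard error, each between the means of 3 treated and 3 control arrays. A rise or fall with a compound is a difference from the controls of the same time, which themselves changed with time. Between times, gained, lost, higher and lower describe that difference and not the level of the treated arrays. The standard error comes from the moderated spread over all arrays of the control family, not from these arrays alone. It can lie above or below the spread seen in the groups compared. For the largest changes named in each main comparison, all 3 treated arrays lay outside the range of the 3 control arrays. Where the control mean lay below log2 4, the level at which genes entered the tests, the change is against background, and the text says so. A fall to a mean below log2 4 is likewise named a fall to background, and its size depends on the background correction. The lists of genes were fixed from general knowledge of each pathway. In 30 list results of the main comparisons the median, the mean and the test differed in sign, and 0 of these lists were called. In the other comparisons this held for 128 list results, 2 of them called, which were the autophagy list in CdCl 12 h and the p53 list in Di 12 h.

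Genes called against the matching controls ranged from 0 in CsA 12 h and Fk 48 h to 7236 in Ota high 24 h.

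**Figure D1:**
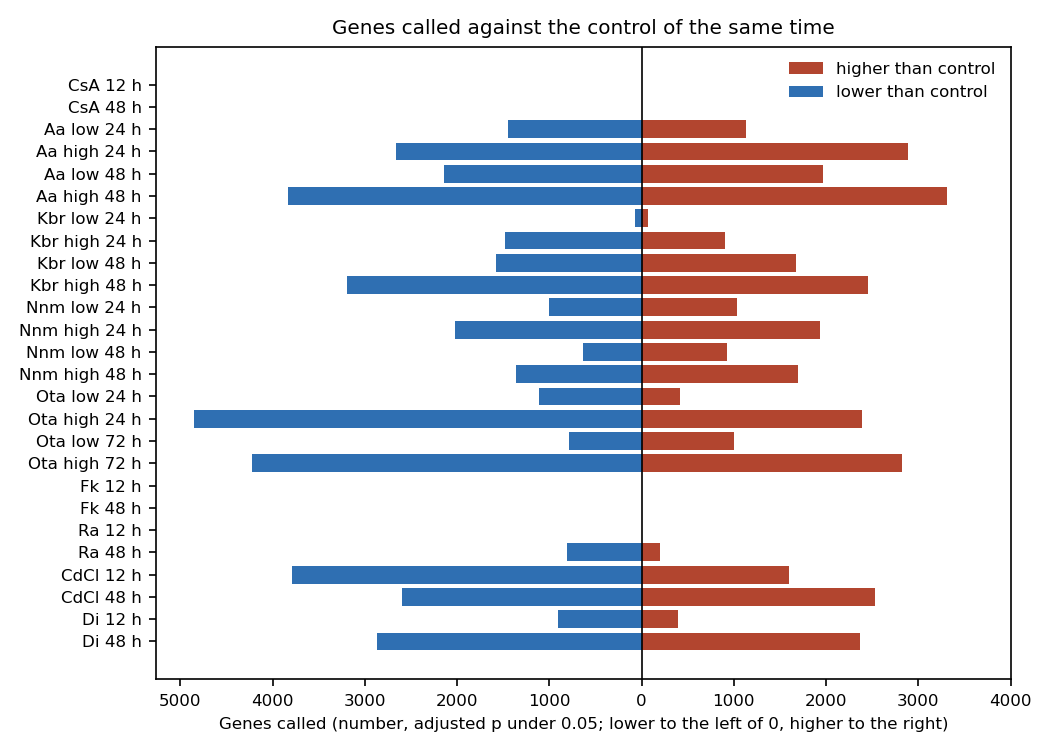
Number of genes called higher (right) and lower (left) than in the matching controls, as bars for each of the 26 treated groups. The longest bar is that of the 4852 genes lower in Ota high 24 h, and CsA, Fk and Ra 12 h have almost no bar.

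Aa at the high dose for 48 h was compared with its controls to find the largest response to this compound, 3 arrays against 3. ATF3, a stress-induced transcription factor, rose by 6.89 ± 0.425 from a control level of 5.00 to 11.9 (adjusted p = 9.35e-09). The amine oxidase gene AOC3 rose by 7.07 ± 0.57, SHISA2 by 7.07 ± 0.443, the carboxyl ester lipase gene CEL by 6.77 ± 0.78 and the muscle glycogen phosphorylase gene PYGM by 6.61 ± 0.314. The control levels of these 4 genes, from 1.92 to 3.25, were background. SYT1, which encodes a calcium sensor of vesicle release, fell by 6.71 ± 0.87 from 9.91 to 3.20 (adjusted p = 7.85e-06). GPR160 fell by 6.64 ± 0.709, the protein kinase C beta gene PRKCB by 6.25 ± 0.673, the receptor tyrosine phosphatase gene PTPRG by 6.07 ± 0.634 and ANK3, which encodes ankyrin G, by 6.02 ± 1.11, and these 5 genes fell to background. In all, limma called 7139 genes, 3311 higher and 3828 lower, and 3639 of them changed at least 2-fold. The 3 prime minus 5 prime difference of the ACTB control probe sets, a sign of RNA quality, was 1.35 in the treated arrays and 0.932 in the controls, with a control SD of 0.196, and was higher in each treated array than in the control with its number.

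In the same comparison the list of polyadenylated histone genes was the only one called. Of its 9 members tested 8 rose and 1 was not called, both over all genes and adjusted over the list alone. H1-2 rose by 3.98 ± 0.214 from 5.08 to 9.05, and H2BC21 by 4.02 ± 0.336 from background. The list's median change was 3.16, and its call (adjusted p = 0.000533) was lost at adjusted p = 0.773 with an estimated correlation. Of 24 p53 targets 11 rose and 6 fell, with GADD45A higher by 3.01 ± 0.184, and of 28 ATF4 targets 12 rose and 9 fell, with STC2 higher by 3.58 ± 0.254 and SLC7A11 lower by 2.48 ± 0.45. Of 20 immediate early genes 10 rose and 3 fell, with FOSB and FOS higher by 5.84 ± 0.484 and 5.03 ± 0.334 from background. These 3 lists were not called (adjusted p = 0.316, 0.464 and 0.129). Of 19 cholesterol synthesis genes 2 rose and 12 fell, 5 were not called, and the list was not called (adjusted p = 0.0563).

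At 24 h the high dose of Aa gave 5546 calls, 2889 higher and 2657 lower, with 2342 of at least 2-fold. CEL rose by 6.36 and the lactase gene LCT by 6.14 from background, while SYT1 fell by 6.81 and EXOC4, which encodes an exocyst subunit, by 6.06, both to background. Of 19 cholesterol genes 15 fell and 4 were not called, and the list was called (adjusted p = 0.000341, and adjusted p = 0.119 with an estimated correlation).

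The low dose of Aa gave 2576 calls at 24 h, 1128 higher and 1448 lower with 792 of at least 2-fold, or 4163 with the replicate block. At 48 h it gave 4111, 1968 higher and 2143 lower with 1364 of at least 2-fold. At 24 h GCNA rose by 4.51, the interferon-induced gene IFI35 fell by 4.14 and NANOS1 by 3.99, both to background. At 48 h CEL rose by 4.79 from background, the glypican gene GPC6 fell by 4.88 and WWOX by 4.87 to background.

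Between the doses of Aa at 48 h, 4971 genes differed, 2249 higher and 2722 lower at the high dose, and 1859 by at least 2-fold. FOSB was higher by 4.70 against background at the low dose, and ANK3, TBC1D5 and FRAS1 were lower by 4.32, 4.12 and 4.07, the first pair at background. The metallothionein list, lower in 6 of 8 members, was called at adjusted p = 0.0437, was not called with the replicate block (adjusted p = 0.0701), and was also lost at adjusted p = 0.682 with an estimated correlation. The change at 48 h differed from that at 24 h for 2092 genes, or 4126 with the replicate block, and without the block 736 of them were higher, 1356 lower and 988 different by at least 2-fold. FOSB gained 5.13 ± 0.684 between the times, and LPP, a focal adhesion gene, lost 3.51, from a change of −2.03 at 24 h to −5.55 at 48 h.

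Kbr at the high dose for 48 h was compared with its 3 controls. HMOX1, the heme oxygenase gene, rose by 3.62 ± 0.819 from 7.84 to 11.5 (adjusted p = 0.000829), ATF3 by 4.33 ± 1.28, ADM by 3.96 ± 0.743 and the endoplasmic reticulum gene SDF2L1 by 3.47 ± 0.631. SCEL, which encodes sciellin, fell by 5.73 ± 0.594 from 9.56 to 3.83 (adjusted p = 7.84e-08), and EFEMP1, a fibulin gene, fell by 5.23 ± 0.341. ENPP3 fell by 5.38 ± 0.721, ENDOD1 by 4.97 ± 0.304 and the sterol reductase gene TM7SF2 by 4.75 ± 0.434, and these 5 genes fell to background. In all 5643 genes were called, 2449 higher and 3194 lower, 2489 of them by at least 2-fold. The upper quartiles of the treated arrays, 6.83 to 6.96, lay below those of the controls, 7.03 to 7.07, and the ACTB difference was 1.13 against 0.952, higher in each treated array than in the control with its number. Such a one-sided ACTB difference was found in all comparisons of Aa, Nnm and Kbr but Kbr low 24 h and Nnm low 48 h. All treated arrays also had lower upper quartiles than all controls in Kbr high 24 h, Ota high 24 h, Ota high 72 h, CdCl 12 h and Di 48 h, and higher ones in Nnm low 48 h and Ota low 72 h.

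Of 25 NRF2 targets tested with Kbr high 48 h, 20 rose, 1 fell and 4 were not called, and adjusted over the list alone 21 rose and 1 fell. GCLM, which encodes a subunit of the glutathione synthesis enzyme, rose by 3.11 ± 0.428. All 23 proteasome genes rose over all genes and also adjusted over the list alone, PSMD12 by 1.95 and PSMC4 by 1.37. Of 17 heat shock genes 13 rose, 1 fell and 3 were not called, with 14 higher and 1 lower adjusted over the list alone. CHORDC1 rose by 2.61 and HSPH1 by 2.18. Of 24 endoplasmic reticulum chaperone genes 15 rose and 9 were not called, 17 being higher adjusted over the list alone, and HSPA5 rose by 1.84. The adjusted p values of these 4 lists were 5.31e-07, 2.17e-09, 5.31e-07 and 4.49e-05. All 4 calls were lost with an estimated correlation, at adjusted p = 0.192, 0.239, 0.239 and 0.489.

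With Kbr high 48 h, 7 of 8 metallothionein genes fell and 1 was not called, with MT1F lower by 2.07 and MT1M by 2.06. Of 17 junction genes 10 fell and 7 were not called, 11 being lower adjusted over the list alone. The cingulin gene CGN fell by 3.27 to background and the E-cadherin gene CDH1 by 2.62. Among 19 cholesterol genes 1 rose, 9 fell and 9 were not called, with LSS lower by 1.65 and INSIG1 by 1.45. Of 28 mitosis genes 18 rose and 10 were not called, KIF2C by 1.35. Adjusted p was 4.49e-05 for metallothioneins, 0.00637 for junctions, 0.00834 for cholesterol and 8.22e-05 for mitosis. With an estimated correlation all 4 were lost, at adjusted p = 0.239, 0.239, 0.489 and 0.547. With the replicate block 11 lists were called instead of 8. The added ones were the TGF-beta targets at adjusted p = 0.0214, the proximal tubule genes at 0.042 and the kidney injury markers at 0.0138, against 0.052, 0.0811 and 0.052 without it. With the block and an estimated correlation 0 lists were called.

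At 24 h the high dose of Kbr gave 2380 calls, 902 higher and 1478 lower with 685 of at least 2-fold. The count was 3801 with the replicate block and 1331 without the shared control array of replicate 1. HMOX1 rose by 3.30 and ADM by 2.54, while SCEL fell by 3.39 and ENDOD1 by 3.34 to background. Of 25 NRF2 targets 14 rose, 1 fell and 10 were not called, 17 being higher adjusted over the list alone, and this list held (adjusted p = 1.09e-10, and adjusted p = 0.0388 with an estimated correlation). In that test the heat shock list, with 13 of 17 members higher, was lost at adjusted p = 0.107. So was the junction list, with 10 of 17 lower, at 0.0616. With the replicate block and an estimated correlation 4 lists held, the junction list at adjusted p = 0.0289 and the NRF2, proteasome and TGF-beta lists at 0.0367, while heat shock stayed lost at 0.062.

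The low dose of Kbr gave 150 calls at 24 h, 74 higher and 76 lower with 48 of at least 2-fold, or 857 with the replicate block. Leaving out the shared control of replicate 1 or 2 gave 5 or 36 calls, and leaving out treated replicate 1, 2 or 3 gave 59, 15 or 29. GCLM rose by 1.77, the periplakin gene PPL fell by 2.04 and ENDOD1 by 1.92. The NRF2 targets and the junction genes held, at adjusted p = 0.014 each with an estimated correlation, with 4 of 25 higher and 3 of 17 lower. Adjusted over the list alone these numbers were 9 and 5. With the block and an estimated correlation the proteasome list (adjusted p = 0.0243) and the TGF-beta list (adjusted p = 0.00995) held as well. At 48 h the low dose gave 3248 calls, 1675 higher and 1573 lower with 992 of at least 2-fold. ATF3 rose by 4.43, SDF2L1 by 3.57, and BLNK, a B-cell linker gene, fell by 3.98 to background.

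Between the doses of Kbr at 48 h, 886 genes differed, 189 higher and 697 lower with 279 of at least 2-fold, and 1965 did so with the replicate block. The count was 408 and 505 without low dose replicates 1 and 2, and 495 without high dose replicate 2. TNFAIP6 was higher by 2.12 at the high dose, and IFI35, HOGA1 and TCEA2 were lower by 2.83, 2.55 and 2.54, at background. Quantile normalization gave 679 calls, 31.5% of them higher instead of 21.3%.

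The change with Kbr at the high dose differed between 24 and 48 h for 209 genes, 64 higher and 145 lower with 128 of at least 2-fold, or 852 with the replicate block. Without treated replicates 1, 2 and 3 of 24 h the count was 94, 121 and 125, and without those of 48 h it was 110, 72 and 394. Without control replicates 2 and 3 of 24 h it was 135 and 45, and without control replicates 1 and 2 of 48 h it was 81 and 105. The replication gene CDC6 gained 1.99 and the complement factor gene CFB lost 3.22 between the times. Of 8 metallothionein genes 6 were lower at the later time, 7 adjusted over the list alone (adjusted p = 3.41e-09, and adjusted p = 0.233 with an estimated correlation).

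Nnm at the high dose for 48 h was compared with the same controls as Kbr. TXNIP, which encodes a thioredoxin-binding protein that limits glucose uptake, rose by 6.38 ± 0.525 from 5.87 to 12.3 (adjusted p = 2.09e-07). The monocarboxylate transporter genes SLC16A14 and SLC16A9 rose by 6.26 ± 0.726 and 4.92 ± 0.958 from background levels of 2.49 and 2.27. The keratin gene KRT20 fell by 3.43 ± 0.63 from 8.75 to 5.33 (adjusted p = 0.00063), the long noncoding RNA UCA1 by 3.38 ± 0.708 and CCDC146 by 3.07 ± 0.671, the last pair to background. CLDN2 fell by 4.03 ± 1.05 and DHRS2 rose by 4.18 ± 1.13 from background, and both calls ended without Nnm replicate 1, at −3.28 and 3.73, or replicate 3, at −3.16 and 3.66. In all 3053 genes were called, 1695 higher and 1358 lower with 1078 of at least 2-fold. The count was 1438 and 1670 without Nnm replicates 1 and 3, and 2019 without control replicate 3. A fit of only the arrays of the comparison called 490 genes and ended the calls of CCDC146, CLDN2, PSMA3, IFIT2, NQO1, H1-2, CDT1, IER3 and HAVCR1 among those named. Replicate 2 of Nnm lay nearer to the controls than the other replicates at both doses and times.

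Of 26 oxidative phosphorylation genes tested with Nnm high 48 h, 20 fell and 6 were not called, with 24 lower adjusted over the list alone. SDHA fell by 1.25 ± 0.213, NDUFS1 by 1.21 ± 0.196 and CYC1 by 1.04 ± 0.158. Of 23 proteasome genes 13 fell and 10 were not called, PSMA3 by 0.80, and 15 were lower adjusted over the list alone. Of 19 cholesterol genes 9 fell and 10 were not called, TM7SF2 by 1.88 and ACAT2 by 1.49, and 13 were lower adjusted over the list alone. Of 17 interferon-induced genes 9 rose and 8 were not called, 10 being higher adjusted over the list alone, and IFIT2, OAS1 and HERC5 rose by 1.86, 1.61 and 1.32. Adjusted p for these 4 lists was 1.36e-12, 9.44e-06, 5.22e-06 and 0.000334. All 4 calls were lost at adjusted p = 0.212, 0.489, 0.231 and 0.231 with an estimated correlation.

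Among the other lists called with Nnm high 48 h, the NRF2 targets rose in 6 members, fell in 2 and were not called in 17. TXNRD1, the thioredoxin reductase gene, rose by 1.65 and NQO1 by 1.39. Of 7 histone genes 3 fell and 4 were not called, H1-2 by 1.32 to background. Of 30 replication genes 7 rose and 23 were not called, with CDT1 higher by 1.48. Of 19 immediate early genes 7 rose, 1 fell and 11 were not called, and IER3 rose by 1.68. Adjusted p was 0.0133, 0.00737, 0.0195 and 0.0195 in that order. These were also lost with an estimated correlation, at adjusted p = 0.489, 0.446, 0.819 and 0.78. Without the Nnm arrays numbered 2, a setting chosen after seeing the data, the oxidative phosphorylation list, lower in 22 members, held at adjusted p = 0.0465 with an estimated correlation, and the replication list was not called (adjusted p = 0.0503).

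At 24 h the high dose of Nnm gave 3967 calls, 1939 higher and 2028 lower with 1335 of at least 2-fold, and 2014 and 2384 without its replicates 1 and 3. SLC16A14 rose by 6.83 from background, and the neuregulin gene NRG1 fell by 3.50. The low dose gave 2044 calls at 24 h, 1036 higher and 1008 lower with 600 of at least 2-fold, or 3522 with the replicate block. That count was 1277 and 767 without control replicates 1 and 3, and 858 and 1029 without Nnm low replicates 1 and 3. SLC16A14 rose by 5.58 from background and the thrombospondin gene THBS1 fell by 4.01. The metallothionein list was called here at adjusted p = 0.0482, was not called with the replicate block (adjusted p = 0.0573), and was lost at adjusted p = 0.821 with an estimated correlation.

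At 48 h the low dose of Nnm gave 1558 calls, 926 higher and 632 lower with 463 of at least 2-fold, or 2948 with the replicate block. Without control replicates 1 and 3 the count was 904 and 806, and without Nnm low replicates 1 and 3 it was 565 and 737. TXNIP rose by 6.19 and KRT20 fell by 3.60. Between the doses of Nnm at 48 h limma called 0 genes, with 569 at unadjusted p < 0.05, and 570 and 1 genes without replicate 2 of the high and of the low dose. Between 24 and 48 h at the high dose it called 0 genes, with 1297 at unadjusted p < 0.05 and 80 calls with the replicate block. That number was 1236 without replicate 2 of 24 h and 208 without replicate 2 of 48 h.

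Ota at the high dose for 72 h was compared with its 3 controls. PLAUR, the urokinase receptor gene, rose by 6.07 ± 0.239 from 4.63 to 10.7 (adjusted p = 3.37e-11). The histone gene H2BC4 rose by 7.06 ± 0.301, AOC3 by 6.94 ± 0.707, SPMIP1 by 6.24 ± 0.36 and the galanin gene GAL by 5.90 ± 0.37, all from background levels under log2 4. METTL23, a methyltransferase gene, fell by 7.80 ± 0.172 from 10.7 to background (adjusted p = 1.15e-13). RUFY1 fell by 6.54 ± 0.363, GPR160 by 6.44 ± 0.283 and HOGA1, which serves hydroxyproline breakdown in mitochondria, by 6.15 ± 0.458, all to background, and TMEM37 by 6.17 ± 0.461. In all 7044 genes were called, 2821 higher and 4223 lower with 4120 of at least 2-fold. The ACTB difference was 1.93 in the treated group and 1.36 in the controls, with a control SD of 0.182, and all treated arrays lay above all controls.

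Of 29 ATF4 targets tested with Ota high 72 h, 1 rose, 25 fell and 3 were not called. DDIT3 was lower by 4.19 ± 0.425, at 8.71 against 12.9 in controls, where it had risen by 4.97 since 24 h. DDIT4 was lower by 3.80 ± 0.137 and AARS1 by 3.67 ± 0.238. Of 24 chaperone genes 1 rose, 14 fell and 9 were not called, with SDF2L1 lower by 4.34 and HYOU1 by 3.12. Of 7 proximal tubule genes 6 fell and 1 was not called, with CDH16 lower by 3.76 and SLC4A4 by 3.40. Of 8 metallothionein genes 7 fell and 1 was not called, MT1F by 2.57. Adjusted p was 3.43e-06, 0.0145, 0.00302 and 0.00338 in that order. With an estimated correlation all 4 calls were lost, at adjusted p = 0.27, 0.66, 0.27 and 0.354.

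Of 10 histone genes tested with Ota high 72 h, 9 rose and 1 fell, with H1-2 higher by 5.54 from background and H2BC6 by 4.54. Of 30 replication genes 22 rose, 4 fell and 4 were not called. MCM10 rose by 4.07 from background, while RFC4 and PRIM1 fell by 4.59 and 2.83. Of 28 mitosis genes 19 rose, 4 fell and 5 were not called, and TTK rose by 1.87. Of 23 proteasome genes 15 rose and 1 fell, PSMD3 rising by 1.81. Of 17 heat shock genes 10 rose and 2 fell, with 11 higher and 2 lower adjusted over the list alone, and BAG3 rose by 2.05. Adjusted p was 2.31e-06, 5.11e-05, 9.36e-05, 1.7e-05 and 0.0027 for these 5 lists. All were lost with an estimated correlation, at adjusted p = 0.0963, 0.317, 0.55, 0.27 and 0.284.

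The low dose of Ota for 72 h gave 1785 calls, 1003 higher and 782 lower with 626 of at least 2-fold. The count was 1170 and 1038 without control replicates 1 and 3, and 1071 and 1155 without treated replicates 1 and 3. DHRS2 rose by 3.51 from background, and IFFO1 fell by 4.32 to background. Replication genes rose in 26 of 30 members and fell in 1, histone genes rose in 8, and both lists held at adjusted p = 0.0198 with an estimated correlation. Endoplasmic reticulum chaperone genes fell in 17 of 24 members, 20 adjusted over the list alone, and ATF4 targets in 14 of 29. Both of these were lost at adjusted p = 0.137 in that test. Between the doses at 72 h, 6441 genes differed, 2325 higher and 4116 lower at the high dose with 3391 of at least 2-fold, and TMEM37, SYNE2 and GPR160 were lower by 6.34, 6.00 and 5.98, the last pair at background.

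At 24 h the high dose of Ota gave 7236 calls, 2384 higher and 4852 lower with 4255 of at least 2-fold. FGF18, a fibroblast growth factor gene, rose by 7.60 from background, and TMEM37 and NBPF20 fell by 7.49 and 6.92 to background. The upper quartile of the arrays averaged 6.49 here against 7.04 in the controls. Quantile normalization shifted the median change of all genes by 0.229 and gave 7362 calls, 43.9% of them higher instead of 32.9%. The low dose at 24 h gave 1527 calls, 414 higher and 1113 lower with 724 of at least 2-fold, and 840 without its replicate 2. The histone gene H2AC6 rose by 5.40, and IFI35 fell by 4.39 to background.

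The change with Ota high differed between 24 and 72 h for 5943 genes, 3647 higher and 2296 lower with 4310 of at least 2-fold. The DNA polymerase gene POLQ moved from −4.54 to 2.99, a gain of 7.53, and the nucleoporin gene NUP85 gained 6.31. ALDH1L2, which encodes a mitochondrial folate enzyme, lost 6.15, with a change of −4.95 at 72 h. Replication genes were higher at the later time in 27 members and lower in 2, and ATF4 targets were lower in 21 and higher in 1. Adjusted p was 5.68e-08 for each, and both were lost at adjusted p = 0.194 with an estimated correlation.

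CdCl for 48 h was compared with the controls it shared with Di. The metallothionein gene MT1M rose by 6.24 ± 0.101 from 8.24 to 14.5 (adjusted p = 1.56e-15), and HMOX1 rose by 6.02 ± 0.0983 from 8.42 to 14.4. The trypsin inhibitor gene SPINK1 rose by 6.12 ± 0.192, ASB5 by 5.76 ± 0.396 and SOCS2, which encodes a suppressor of cytokine signalling, by 5.62 ± 0.293, all from background levels of 2.92 to 3.29. BLNK fell by 5.49 ± 0.432 from 8.48 to 2.99 (adjusted p = 9.55e-08), TMT1A by 5.19 ± 0.246, RASSF10 by 4.30 ± 0.215, the homeobox gene IRX5 by 4.22 ± 0.265 and ENPP3 by 3.95 ± 0.436. BLNK, IRX5 and ENPP3 fell to background. In all 5130 genes were called, 2529 higher and 2601 lower with 1194 of at least 2-fold.

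All 8 metallothionein genes rose with CdCl 48 h, MT1G by 4.19 and MT1X by 2.55. Of 27 NRF2 targets 21 rose, 1 fell and 5 were not called, with 23 higher and 1 lower adjusted over the list alone, and AKR1C1 rose by 2.89. Of 19 heat shock genes 15 rose and 4 were not called, BAG3 by 1.87 and HSPA6 by 3.92 from background. Of 24 endoplasmic reticulum chaperone genes 18 rose and 6 were not called, DNAJB11 by 0.94. Of 30 replication genes 1 rose, 25 fell and 4 were not called, CDT1 by 2.80 and MCM5 by 2.09. Of 28 mitosis genes 25 fell and 3 were not called, CDK1 by 1.54. Of 22 autophagy genes 14 rose, 1 fell and 7 were not called, with the cathepsin gene CTSL higher by 1.45. These 7 lists held with an estimated correlation. Adjusted p in that test was 0.000979 for the metallothionein, replication and mitosis lists, 0.000147 for NRF2 targets, 0.0114 for heat shock, 0.0187 for chaperones and 0.00203 for autophagy.

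A further 5 lists were called with CdCl 48 h only at the preset correlation. Of 23 proteasome genes 12 rose and 11 were not called (adjusted p = 0.0036, and adjusted p = 0.0762 with an estimated correlation). Of 19 cholesterol genes 2 rose and 10 fell (adjusted p = 0.0331, and adjusted p = 0.123 with an estimated correlation). Of 24 glycolysis and hypoxia genes 10 rose and 4 fell, with SLC2A1 higher by 1.42, and that call was lost at adjusted p = 0.131 in that test. Of 7 proximal tubule genes 2 rose and 4 fell, with CDH16 lower by 3.48, and that call was lost at adjusted p = 0.17 in that test. Of 20 immediate early genes 9 rose and 2 fell, and that call was lost at adjusted p = 0.14 in that test.

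At 12 h CdCl gave 5383 calls, 1598 higher and 3785 lower with 1030 of at least 2-fold. The heat shock gene HSPA6 rose by 7.85 ± 0.373 from background to 10.7, and ATF3 by 7.16 ± 0.275 from 4.61 to 11.8. CCDC146 fell by 3.09 and the helicase gene BLM by 2.88. All 12 lists called at 12 h held with an estimated correlation. Among them 23 of 27 NRF2 targets rose (adjusted p = 6.55e-06 in that test), 18 of 19 heat shock genes rose (adjusted p = 0.000216), and 29 of 30 replication genes fell (adjusted p = 0.00138). ATF4 targets rose in 19 members and fell in 2, with adjusted p = 9.23e-05, and 12 of 19 inflammatory genes rose and 2 fell, with adjusted p = 0.00138. The autophagy list rose in 8 members and fell in 3, with a mean change of 0.293 and a median of −0.0237.

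The change with CdCl differed between 12 and 48 h for 3363 genes, 2331 higher and 1032 lower with 898 of at least 2-fold. The proton pump gene ATP6V0D2 gained 4.04, with a change of 4.03 at 48 h, while ATF3 moved from 7.16 to 1.95 and SLC7A11 from 4.74 to 0.55. ATF4 targets were lower at the later time in 24 members (adjusted p = 1.08e-20, and adjusted p = 1.7e-05 with an estimated correlation). Metallothionein genes were higher in 7 of 8 members, a list that held at adjusted p = 0.02 in that test.

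Di for 48 h was compared with the same controls as CdCl. HMOX1 rose by 5.36 ± 0.0983 from 8.42 to 13.8 (adjusted p = 2.55e-14) and MAP2, a microtubule-associated protein gene, by 5.20 ± 0.167 from 6.82 to 12.0. NMRAL2P rose by 5.83 ± 0.335, the WNT inhibitor gene DKK1 by 5.25 ± 0.287 and SNAI2, which encodes a repressor of epithelial genes, by 5.09 ± 0.247, all from background. CLDN2, which encodes a pore-forming claudin of the proximal tubule, fell by 5.88 ± 0.192 from 9.42 to 3.54 (adjusted p = 5.03e-12). TMT1A fell by 5.58 ± 0.246, the basement membrane collagen gene COL4A3 by 5.24 ± 0.337, BLNK by 5.06 ± 0.432 and the ephrin receptor gene EPHA4 by 4.58 ± 0.199. Of these all but TMT1A fell to background. In all 5231 genes were called, 2368 higher and 2863 lower with 1438 of at least 2-fold.

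All 27 NRF2 targets rose with Di 48 h, with a median change of 2.17, and AKR1C1 rose by 4.83. All 28 mitosis genes fell, KIF20A by 4.54 to background, and 27 of 30 replication genes fell, RRM2 by 3.12 and MCM7 by 2.98. Of 29 ATF4 targets 19 rose, 3 fell and 7 were not called, ATF3 by 2.94 and STC2 by 2.83. Of 8 metallothionein genes 1 rose and 7 fell, MT1F by 1.32. Of 7 proximal tubule genes 1 rose and 6 fell, with the cadherin gene CDH6 lower by 3.51 and SLC4A4 by 3.11. With an estimated correlation the adjusted p of these lists was 4.02e-06, 0.00019, 0.000506, 0.00548, 0.0159 and 0.0182, so that all 6 held.

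Heat shock genes rose in 14 of 19 members and fell in 1 with Di 48 h, DNAJB4 by 2.09. Chaperone genes rose in 18 of 24, 19 adjusted over the list alone, and proteasome genes in 17 of 23, also 19 adjusted over the list alone. These 3 lists held at adjusted p = 0.00931 with an estimated correlation. Autophagy genes rose in 13 of 22 members and fell in 3, CTSL by 1.93, and held at adjusted p = 0.00548. The p53 targets rose in 11 of 24 members and fell in 2, with GDF15 higher by 2.10, and that call was lost (adjusted p = 0.00092, and adjusted p = 0.0614 with an estimated correlation). The glycolysis list, 12 members higher and 5 lower of 24, was lost at adjusted p = 0.104 in that test. The immediate early list, 10 higher and 4 lower of 20, was lost at adjusted p = 0.132 in that test.

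At 12 h Di gave 1308 calls, 399 higher and 909 lower with 69 of at least 2-fold. The count was 599 and 702 without control replicates 2 and 3, 48 with all arrays in 1 fit, 216 in a fit of only the arrays of the comparison and 776 without _x_at and _s_at probe sets. Quantile normalization gave 1205 calls, 42.4% of them higher instead of 30.5%. The small GTPase gene RIT1 rose by 2.38, and TXNIP and BLNK fell by 2.12 and 1.64. The ACTB difference was 1.43 in the treated arrays and 1.95 in the controls, and all treated arrays lay below all controls. NRF2 targets rose in 7 of 27 members and held at adjusted p = 0.00463 with an estimated correlation. Proteasome genes rose in 5 of 23 and held at adjusted p = 0.0427, while the p53 list, called with a median change of −0.00416, was lost at adjusted p = 0.28 in that test. The change differed between 12 and 48 h for 3715 genes, 1929 higher and 1786 lower with 1312 of at least 2-fold. CLDN2 moved from −0.02 to −5.88 and MAP2 gained 5.53, and 26 of 27 NRF2 targets were higher at the later time (adjusted p = 5.25e-06 with an estimated correlation).

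Ra for 48 h was compared with the controls it shared with Fk. INHBE was lower by 6.69 ± 1.24, at 5.14 against 11.8 (adjusted p = 0.0113). ANK2 was lower by 3.98 ± 0.572, at 5.25 against 9.24 (adjusted p = 0.00421), and ALDH1L2 by 3.78 ± 0.574. The 12 h controls lay at 4.54 for INHBE and 5.57 for ANK2, near the Ra 48 h level. CTH was lower by 3.90 ± 0.943 and SLC7A11 by 3.68 ± 0.783. SHISA2 was higher by 3.06 ± 0.705, LYPD1 by 2.28 ± 0.452, NT5E by 2.20 ± 0.424, CTHRC1 by 2.15 ± 0.482 and ASF1B by 2.00 ± 0.344. In all 1016 genes were called, 204 higher and 812 lower with 619 of at least 2-fold.

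These counts with Ra 48 h depended on single arrays. Without control replicates 1, 2 and 3 there were 67, 25 and 1574 calls, and without Ra replicates 1, 2 and 3 there were 2361, 608 and 546. Of 29 genes named under the rule, the calls of 23, 27 and 1 ended without control replicates 1, 2 and 3, and those of 1, 11 and 14 without Ra replicates 1, 2 and 3. The calls of ANK2 and ALDH1L2 held without each array, but a fit of only the arrays of the comparison called 0 genes. Ra replicate 2 had an upper quartile of 6.09, the lowest of all arrays. Quantile normalization shifted the median change of all genes by 0.23 and gave 1734 calls, 50.6% of them higher instead of 20.1%.

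Of 29 ATF4 targets 25 were lower and 4 not called with Ra 48 h, 28 adjusted over the list alone, with a median change of −2.05. DDIT3 was lower by 3.65 ± 0.802, at 9.96 beside 8.45 in the 12 h controls. Of 30 replication genes 12 rose and 18 were not called, 23 being higher and 1 lower adjusted over the list alone. CCNE2 rose by 1.90 and CCNE1 by 1.59. Mitosis genes rose in 1 of 28 members, 11 adjusted over the list alone, and MKI67 rose by 1.13. Chaperone genes fell in 5 of 24 members, 17 adjusted over the list alone, with HERPUD1 lower by 2.48. Adjusted p was 2.44e-15, 1.01e-19, 3.69e-15 and 4.92e-05 for these lists. With an estimated correlation all 4 were lost, at adjusted p = 0.489, 0.489, 0.623 and 0.932. The metallothionein, cholesterol, TGF-beta and immediate early lists, with at most 1 called member each, were called and lost at adjusted p = 0.786, 0.962, 0.932 and 0.962 in that test.

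At 12 h Ra gave 4 calls, all higher. These were KLHL24 by 2.07 ± 0.315, UBALD2 by 1.92 ± 0.255, EVC by 1.42 ± 0.224 and ZNF362 by 1.26 ± 0.203, the last pair chosen after their values were seen. Leaving out control replicate 1 left 1 call, and leaving out control replicate 2 or 3 or Ra replicate 1 or 2 left 0 in the limma fit, which had 780 genes at unadjusted p < 0.05 with all arrays. Quantile normalization gave 27 calls, 66.7% of them higher instead of 100%. Between 12 and 48 h the change with Ra differed for 5 genes, and in all of them it was lower at the later time. ALDH1L2 lost 5.52 ± 0.812, ANK2 5.50 ± 0.809 and DIRC3 2.74 ± 0.392, and ENPP2 lost 2.25 ± 0.373 and ENPEP 1.71 ± 0.24, this pair chosen after their values were seen. Quantile normalization gave 120 calls there, 40.8% of them higher.

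The count of 5 for Ra between the times was 3, 0 and 0 without control replicates 1, 2 and 3 of 12 h, and 0 without Ra replicates 1 and 3 of 12 h. It was 0, 0 and 69 without control replicates 1, 2 and 3 of 48 h, and 735, 9 and 8 without Ra replicates 1, 2 and 3 of 48 h. The ATF4 list was lower at the later time in 24 of 29 members adjusted over the list alone (adjusted p = 6.19e-16, and adjusted p = 0.492 with an estimated correlation).

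CsA, Fk and their times gave few single genes. In CsA 48 h limma called 1 gene, the noncoding EML2-AS1, which rose by 1.28 ± 0.103 from background to 4.18 (adjusted p = 0.00193), with 1401 genes at unadjusted p < 0.05. With the replicate block 206 genes were called, 85 higher and 121 lower with 98 of at least 2-fold. The count was 87, 0 and 0 without CsA replicates 1, 2 and 3, and 2 without control replicate 3. In CsA 12 h limma called 0 genes, with 88 at unadjusted p < 0.05, and 0 between the times, with 382. In Fk 12 h it called 1 gene, TCF15, higher by 1.30 ± 0.181, and 0 without any of the 3 control arrays or without Fk replicate 1 or 3. In Fk 48 h limma called 0 genes, with 348 at unadjusted p < 0.05, and 0 between the times, with 231.

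Gene lists of CsA 48 h were called although 0 of their members were. The replication list was lower with a median change of −1.26, and 29 of its 30 members were lower adjusted over the list alone. The mitosis list was lower, the chaperone list higher with 6 of 24 members adjusted over the list alone, and the cholesterol list lower with 4 of 19. ATF4 targets were higher with 2 members adjusted over the list alone, and so was the autophagy list. Adjusted p for these 6 lists was 1.24e-25, 2.8e-10, 2.8e-10, 0.000717, 0.00286 and 0.0225. All were lost with an estimated correlation, at adjusted p = 0.388 for the replication and cholesterol lists and 0.417 for the other 4. With the replicate block 10 lists were called, adding the metallothioneins at adjusted p = 0.000593, inflammatory genes at 0.00899, TGF-beta targets at 0.046 and proximal tubule genes at 0.00502, but 0 with the block and an estimated correlation.

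In Fk 48 h 8 lists were called, again with 0 called members. The cholesterol list was lower at a median of −0.457 and the glycolysis list higher, at adjusted p = 1.43e-09 and 8.92e-08, and the histone list was lower at adjusted p = 0.000728. These 3 were lost at adjusted p = 0.322 with an estimated correlation. The metallothionein and TGF-beta lists were higher and the proximal tubule list lower, all lost at adjusted p = 0.712 in that test. The replication list was lower and the immediate early list higher, both lost at adjusted p = 0.944 in that test.

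**Figure D2:**
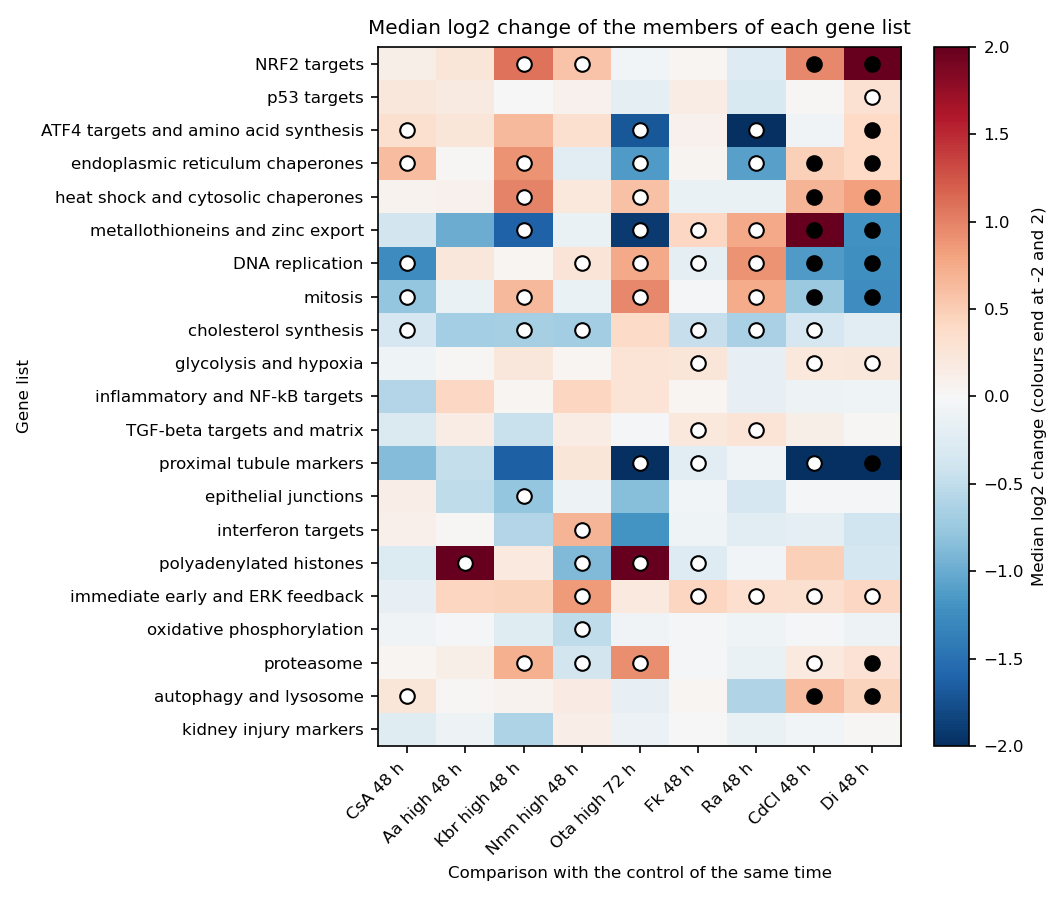
Median log2 change of each gene list (vertical) in the 9 main comparisons (horizontal), with colours ending at −2 and 2. White circles mark calls at the preset correlation and black circles calls that also held with an estimated one, which occur only with CdCl and Di.

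Of 23 lists, that of markers of other kidney and blood cells had 0 members tested outside the Ota family and 1 within it. The AhR targets had 4 members tested in most families, too few for the list test. HAVCR1, the kidney injury molecule gene, fell with Aa high 48 h by 1.05 ± 0.154, with Kbr high 48 h by 1.77 ± 0.339, with CdCl 48 h by 1.03 ± 0.133 and with Di 48 h by 1.46 ± 0.133. At 12 h it rose, by 0.59 ± 0.133 with CdCl (adjusted p = 0.00208) and by 1.06 ± 0.133 with Di (adjusted p = 0.000501). With Nnm high 48 h it fell by 0.91 ± 0.339, a call that ended without control replicates 1, 2 and 3, at −0.98, −0.89 and −0.87, or Nnm replicates 1 and 3, at −0.52 and −0.84. The lipocalin gene LCN2 rose with CdCl 48 h by 2.94 ± 0.202 and with Di 48 h by 2.17 ± 0.202.

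**Figure D3:**
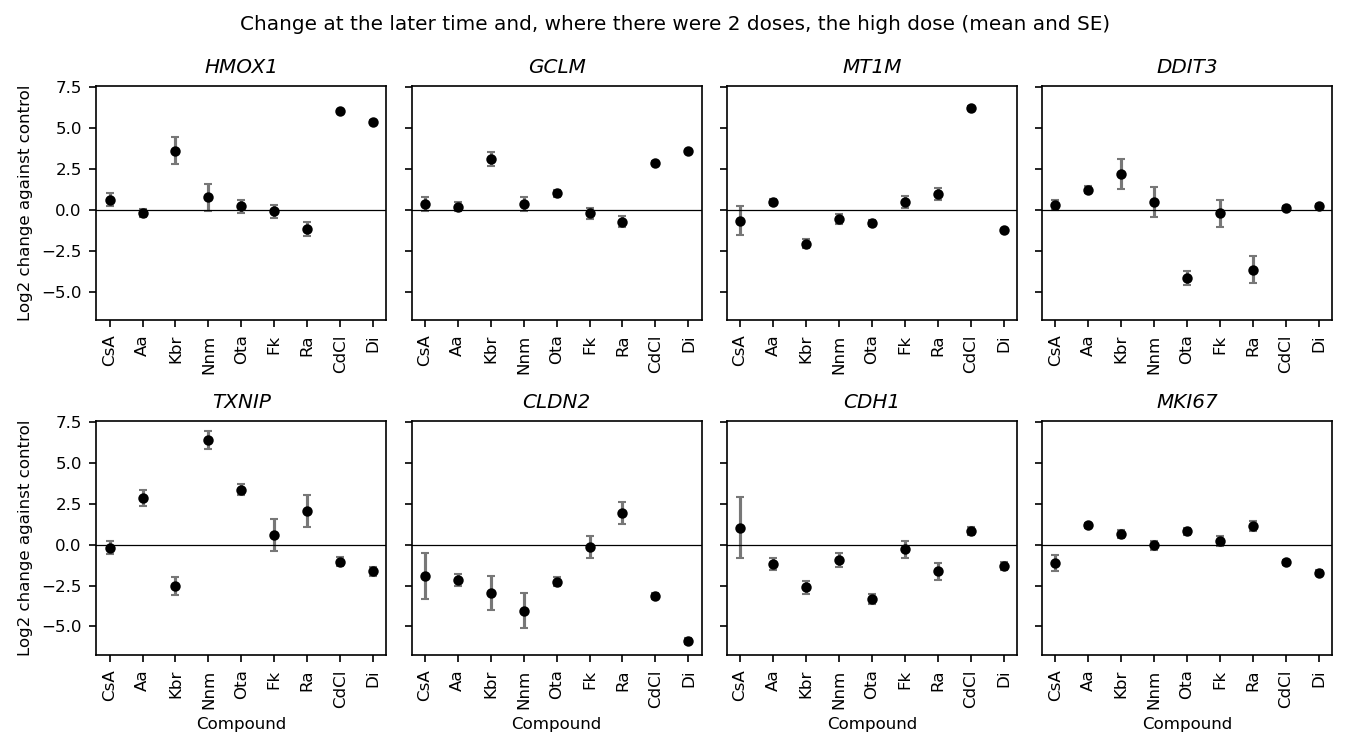
Change in log2 units with its standard error for HMOX1, GCLM, MT1M, DDIT3, TXNIP, CLDN2, CDH1 and MKI67 in the 9 main comparisons. MT1M rose by 6.24 with CdCl, whereas it fell by 1.26 with Di.

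The compounds sharing controls were also compared directly, which takes the controls out of the difference. Nnm high and Kbr high at 48 h differed in 6255 genes, 3585 higher and 2670 lower with Nnm, and 3129 by at least 2-fold. TXNIP was higher by 8.91 ± 0.525 with Nnm, at 12.3 against a background level of 3.34, and PCLO, a presynaptic scaffold gene, by 6.33. NRG1 was lower by 4.86, SDF2L1 by 4.44 and UCA1 by 3.80 at background. All 23 proteasome genes were lower with Nnm, 19 of 24 chaperone genes were lower and 14 of 17 interferon-induced genes were higher. The proteasome and interferon lists were lost at adjusted p = 0.291 with an estimated correlation, and the chaperone list at adjusted p = 0.382.

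CdCl and Di at 48 h differed in 4703 genes, 2607 higher and 2096 lower with CdCl, and 872 by at least 2-fold. MT1M was higher by 7.50 ± 0.101 with CdCl, at 14.5 against 6.98, and SOCS2 by 6.15 against background. TM6SF1 was lower by 2.83, the diacylglycerol kinase gene DGKG by 2.70 and F2RL2 by 2.68, all at background. All 8 metallothionein genes were higher with CdCl, 23 of 27 NRF2 targets were lower and 1 higher, 21 ATF4 targets were lower and 1 higher, 22 mitosis genes were higher and 1 lower, and 16 of 24 p53 targets were lower. These 5 lists held, at adjusted p = 0.000667, 8.11e-05, 0.0013, 0.0053 and 0.0187 with an estimated correlation.

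Fk and Ra at 48 h differed in 805 genes, 692 higher and 113 lower with Fk, and 522 by at least 2-fold. INHBE was higher by 6.33 ± 1.24 with Fk, ANK2 by 4.36 and ITPKA by 4.06, and TM4SF4, BLM and CBLN2 were lower by 2.40, 2.17 and 2.13, TM4SF4 and CBLN2 at background. The count was 58, 124 and 1363 without Fk replicates 1, 2 and 3, and 2282, 363 and 374 without Ra replicates 1, 2 and 3. A fit of only the arrays of the comparison called 0 genes. Quantile normalization gave 1360 calls, 48.3% of them higher instead of 86%. ATF4 targets were higher in 25 of 29 members, 28 adjusted over the list alone (adjusted p = 1.09e-17, and adjusted p = 0.367 with an estimated correlation).

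Across the 9 main comparisons and the 10523 genes tested in all, 248 genes were called higher in at least 5, where 31.6 would fall there if the lists were independent, and 556 were called lower, where 103 would. ABCA12, SLITRK4, BCKDHB and MMAB were lower in 7. CLDN2, the transporter genes SLC6A13 and SLC4A4, EPHA4, TM7SF2 and ZFHX4-AS1 were lower in 6. CLDN2 fell by 2.16 with Aa, 2.26 with Ota, 3.12 with CdCl and 5.88 with Di. Part of the excess over independent lists may come from the shared controls of 3 pairs of compounds.

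The change of all genes was compared between compounds that shared controls, beside values simulated for unchanged groups against the same controls, across 10523 genes that are not independent replicates. CdCl and Di at 48 h had r = 0.663 where 0.501 was simulated, and a covariance of 0.311 where 0.0151 was simulated. They shared 1298 genes called higher and 1543 called lower, where 513 and 667 would be shared by independent lists. Nnm high and Kbr high at 48 h had r = 0.136 where 0.499 was simulated, with a covariance of 0.0786 against 0.0355. They shared 379 genes higher and 485 lower, where independent lists would share 352 and 398. Fk and Ra at 48 h had r = 0.323 where 0.5 was simulated, a covariance of 0.0521 against 0.0534, and 0 shared calls in limma, since Fk had 0.

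The 26 responses were divided in 3 clusters by their correlation over 8021 genes. The first held CsA 12 h alone, another the 8 responses of Nnm, Fk and Ra, and the last the other 17. With complete linkage this did not hold, since Fk and Ra at 48 h joined Aa and Ota, and CsA 12 h joined CsA 48 h, Kbr, CdCl and Di. Ra 48 h had its highest r, 0.424, with Ota low 72 h. The highest correlations across genes lay between the doses of Kbr, at r = 0.932 for 24 h and 0.929 for 48 h, between the times of Kbr high, at r = 0.896, and between the doses of Nnm at 48 h, at r = 0.891. The pairs of doses share controls.

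**Figure D4:**
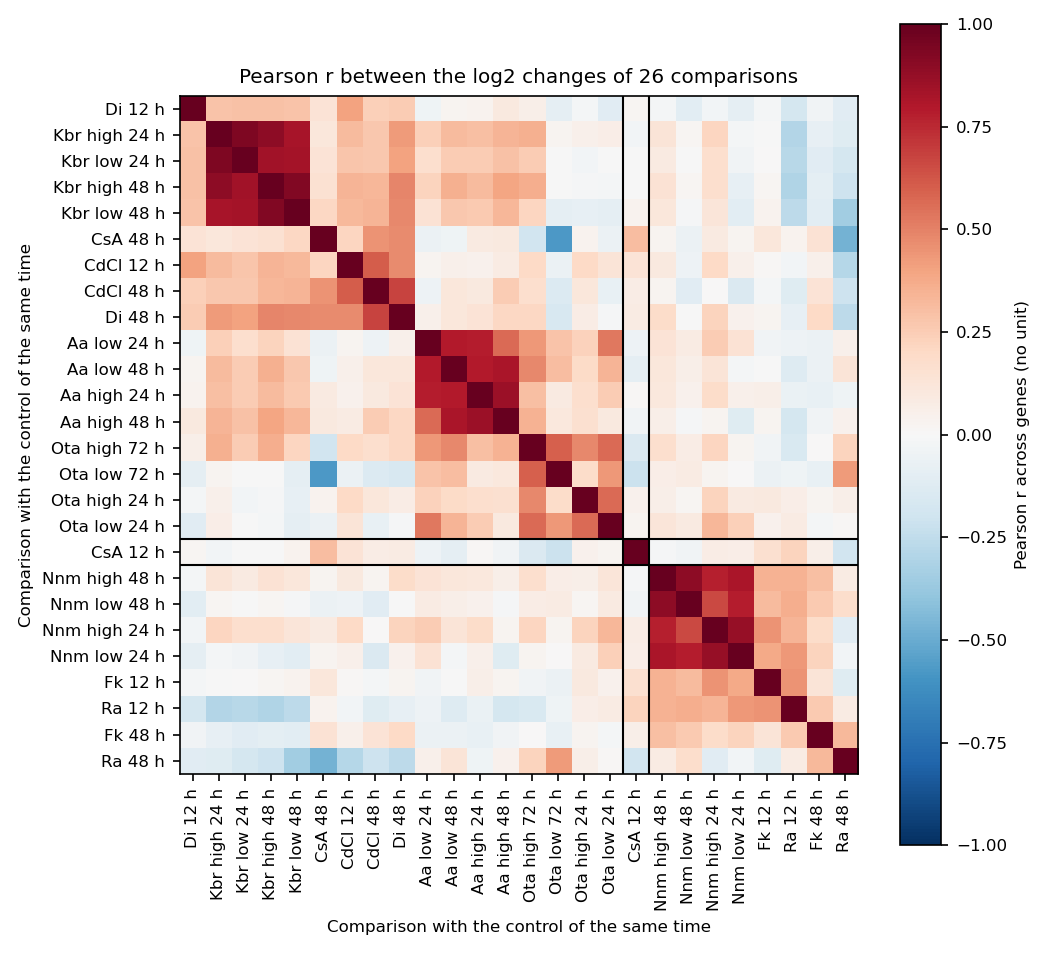
Pearson r across 8021 genes between the log2 changes of the 26 treated groups, in the order of the clustering tree, with lines between the 3 clusters. The block of Nnm, Fk and Ra holds 8 responses.

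The 36 control arrays differed between control families. Over 11100 genes their first 2 principal components held 39.1% and 21% of the variance. Of all variance 42.2% lay between families, 36.2% between times and 76.4% between the groups of family and time. The median SD within groups was 0.278 for CsA, 0.224 for Aa, 0.26 for Nnm with Kbr, 0.257 for Ota, 0.325 for Fk with Ra and 0.163 for CdCl with Di, so that equal changes were called more readily with CdCl and Di. Only the CsA labels carry a lab number, 3, so that lab and family cannot be told apart for CsA.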

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

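The splits were tests chosen after the results were seen. For 6 compounds the change from the controls differed between the times by a test of that difference, in 2092 genes for Aa high, 209 for Kbr high, 5943 for Ota high, 5 for Ra, 3363 for CdCl and 3715 for Di. They included FOSB with Aa, POLQ with Ota, ATF3 with CdCl and CLDN2 with Di. In 100 splits of the 12 arrays of each, drawn over both times, 1 split gave as many genes for Ota, 1 for Di, 3 for CdCl and 2 for Ra, the real split included, and the highest of the others gave 4260, 2892, 4689 and 404 genes. These splits mix treated and control arrays, so treatment enters them. In 100 draws of residuals from a fit without the time difference, treatment and time effects stay. Of the draws 2 gave as many for Ota and 1 each for Di, CdCl and Ra. The highest of the others gave 6811, 737, 317 and 1. The draws argue against chance, at unadjusted shares under 0.05, but for Ra the 5 genes were 0 without any of 6 single arrays. For Aa 6 splits gave as many, the highest of the others 4913, and for Kbr 5 splits, the highest of the others 3988. Drawn within the numbers that pair these arrays and fitted with the replicate block, 6 splits gave as many for Aa and 13 for Kbr, the highest of the others 7717 and 4978, whereas draws of residuals within numbers gave as many in 2 each, the highest of the others 4728 and 2194. The tests part, so that chance is not excluded for either. Where limma called 0 genes between the times, for CsA, Nnm and Fk, all 100 splits gave as many by construction. The highest other split gave 4548, 5553 and 1000 genes, and the highest draw of residuals, with the replicate block for CsA and Nnm, 1471, 3423 and 1. Splits far above the real count can therefore hold the effect of treatment besides a structure of the samples, and for Fk no such structure was shown. The later controls also differed from the earlier ones.

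With Ota high 72 h the 3 prime minus 5 prime difference of the ACTB control probe sets, which no comparison of genes used, was 0.564 above the controls, and all 3 treated arrays lay above all 3 controls. This measure follows RNA quality, and the changes in Ota high 72 h were not corrected for it.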

How the results depend on the processing

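The settings that left out the CsA arrays numbered 3, the Nnm arrays numbered 2, or Ra 48 h array 2 with Fk 12 h array 3, the block joined with an estimated correlation, and every test of the control cultures were chosen after seeing the data, and the other settings were planned. Of 42 counts of genes, 11 kept within 1.5 times under every planned setting and without each array. These were Aa high at 24 and 48 h, Aa low 48 h, Kbr high and low at 48 h, Ota high at 24 and 72 h, the dose differences of Aa and Ota, the time difference of Ota and Nnm against Kbr. All counts here are of genes called by limma, and unless a cause is given it was not tested. Signal over background on arrays limits changes from or to levels under log2 4, whose size depends on the background correction, and no other correction was tested.

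Without the filter the counts were 11 in CsA 48 h, 4 in Fk 12 h, 11 in Ra 12 h, 3 in Fk 48 h, 473 in Ra 48 h, 2 between the Nnm doses, 1 between the times of CsA, 1 between those of Fk and 321 in Fk against Ra. With the filter at log2 6 they were 0 in CsA 48 h and 20 between the times of Ra. With the mean of all probe sets they were 2 in CsA 48 h, 2 in Ra 12 h, 2 in Fk 48 h, 1 between the times of Fk and 20 between those of Ra. Without _x_at and _s_at probe sets they were 776 in Di 12 h, 17 between the times of Ra, 508 in Fk against Ra and 948 in the CsA control cultures between the times. With the trend option of limma they were 0 in Fk 12 h, 2 in Ra 12 h, 12 between the times of Ra and 236 in the Aa control cultures.

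Quantile normalization gave 0 in Fk 12 h, 27 in Ra 12 h, 1734 in Ra 48 h, 120 between the times of Ra, 1360 in Fk against Ra and 2699 in the control cultures of Fk and Ra.

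A fit of all arrays at once shares 1 spread between families. It gave 1 in CsA 12 h, 596 in CsA 48 h, 87 in Kbr low 24 h, 34 in Fk 12 h, 120 in Ra 12 h, 14 in Fk 48 h and 3370 in Ra 48 h. In the family with the smallest spread it gave fewer, with 2783 in CdCl 12 h, 2809 in CdCl 48 h, 48 in Di 12 h, 3046 in Di 48 h, 663 and 1266 between the times of CdCl and Di, and 2205 in CdCl against Di. Between the Nnm doses it gave 23, and between the times 29 for CsA, 1347 for Aa, 124 for Kbr, 19 for Nnm and 1562 for Ra. Fk against Ra gave 3188. In the control cultures it gave 2618 for CsA, 14 for Aa, 10 for Nnm with Kbr, 3425 for Fk with Ra and 3233 for CdCl with Di. The lists called in CsA 48 h were 10, and genes shared by compounds were 147 higher.

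A fit of only the arrays of a comparison leaves fewer degrees of freedom and the comparison's own spread. It gave 0 in CsA 48 h, 3704 in Kbr high 24 h, 499 in Kbr low 24 h, 611 in Nnm high 24 h, 994 in Nnm low 24 h, 490 in Nnm high 48 h and 750 in Nnm low 48 h. It gave 2319 in Ota low 24 h, 3560 in Ota low 72 h, 0 in Fk 12 h, 588 in Ra 12 h, 0 in Ra 48 h and 216 in Di 12 h. Between the times it gave 542 for Kbr and 8 for Ra, and Fk against Ra gave 0. In the control cultures it gave 532 for CsA, 0 for Aa, 8 for Nnm with Kbr and 3072 for Fk with Ra.

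The replicate block gave 206 in CsA 48 h, 4163 in Aa low 24 h, 3801 in Kbr high 24 h, 857 in Kbr low 24 h, 3522 in Nnm low 24 h, 2948 in Nnm low 48 h, 1965 between the Kbr doses, and 4126, 852 and 80 between the times of Aa, Kbr and Nnm. In the control cultures the block gave 3146 for CsA, 1555 for Aa and 852 for Nnm with Kbr. In Fk with Ra, where the numbers did not pair the samples, the block gave 0 in Fk 12 h and 82 between the times of Ra. The lists called with the block were 10 in CsA 48 h. Apart from the values given here and beside the results, the block moved no count by over 1.5 times.

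With an estimated correlation the lists called were 0 in CsA 48 h, 0 in Aa high 48 h, 0 in Kbr high 48 h, 0 in Nnm high 48 h, 0 in Ota high 72 h, 0 in Fk 48 h, 0 in Ra 48 h and 7 in CdCl 48 h. With the replicate block and an estimated correlation they were also 0 in the first 7 of these and 7 in CdCl 48 h. Of 73 list calls in the main comparisons 56 ended with an estimated correlation, 7 with all arrays in 1 fit, 4 with quantile normalization, 4 with the mean of probe sets and 2 with the block.

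Leaving out the CsA arrays numbered 3 gave 0 in CsA 48 h and 10 lists called. Leaving out the Nnm arrays numbered 2 gave 4100 in Nnm low 24 h, 5288 in Nnm high 48 h, 3575 in Nnm low 48 h, 1033 between the doses and 1880 between the times. Leaving out Ra 48 h array 2 and Fk 12 h array 3 gave 0 in Fk 12 h, 224 in Ra 12 h, 1 in Fk 48 h, 1542 in Ra 48 h, 201 between the times of Ra and 3806 in their control cultures. Asking for 6 of 9 comparisons gave 24 shared genes higher and 79 lower, and asking for 2-fold gave 27 and 134. Complete linkage gave a largest cluster of 10 instead of 17 responses, and 10 responses fell in another cluster.

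Without each array in turn, the lowest and highest counts were 0 and 87 in CsA 48 h, 1331 and 2165 in Kbr high 24 h, 5 and 179 in Kbr low 24 h, 2014 and 5230 in Nnm high 24 h, 767 and 2520 in Nnm low 24 h, 1438 and 4376 in Nnm high 48 h, and 565 and 2112 in Nnm low 48 h. They were 840 and 1305 in Ota low 24 h, 1038 and 1422 in Ota low 72 h, 0 and 1 in Fk 12 h, 0 and 3 in Ra 12 h, 25 and 2361 in Ra 48 h, and 599 and 1097 in Di 12 h. They were 408 and 789 between the Kbr doses and 0 and 570 between the Nnm doses. Between the times they were 45 and 394 for Kbr, 0 and 1236 for Nnm, and 0 and 735 for Ra, and in Fk against Ra 58 and 2282. In the control cultures they were 583 and 1339 for CsA, 10 and 453 for Aa, 2 and 103 for Nnm with Kbr, and 613 and 2024 for Fk with Ra. The arrays that moved a count by over 1.5 times are named beside each count, and 226 of 306 counts kept within 1.5 times.

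Of the genes named, the calls that ended under at least 1 setting were 1 of 1 in CsA 48 h, 2 of 54 in Aa high 48 h, 3 of 52 in Kbr high 48 h, 37 of 54 in Nnm high 48 h, 2 of 61 in Ota high 72 h, 29 of 29 in Ra 48 h, 8 of 62 in CdCl 48 h and 4 of 62 in Di 48 h. Only IDI1 in CdCl 48 h changed direction, from −0.62 to 0.0416 without _x_at and _s_at probe sets, where another probe set stood for the gene.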

Other observations

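The comparisons of control cultures, the splits of the arrays, the tests of very long genes with Aa, all tests of Nnm replicate 2 and the test of RNA degradation with Aa and Ota were chosen only after the results were seen.

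The control cultures changed from 24 to 48 h for Aa and Nnm with Kbr, 24 to 72 h for Ota and 12 to 48 h otherwise. The ATF4 targets rose between the earlier and later controls in 25 of 29 members for CsA, 28 for Ota, 25 for Fk with Ra and 28 for CdCl with Di, against 2 of 28 for Aa and 0 of 29 for Nnm with Kbr, where the list was also called. DDIT3 rose by 5.44, 4.97, 5.16 and 5.05 and INHBE by 5.60, 5.54, 7.29 and 5.15 in the first 4 families. DDIT3 rose by 1.02 for Aa, and the other changes, 1.82 for INHBE with Aa and 1.58 and 2.38 for Nnm with Kbr, were not called, but INHBE with Aa was with the replicate block. The list held with an estimated correlation for CsA (adjusted p = 0.0271, but adjusted p = 0.206 with the replicate block as well), Ota (adjusted p = 0.0149) and CdCl with Di (adjusted p = 5.05e-06), and was lost for Fk with Ra, Aa and Nnm with Kbr at adjusted p = 0.459, 0.258 and 0.895 with an estimated correlation. Replication genes fell in 13 of 30 members for CsA, 27 for Ota, 25 for Fk with Ra, 28 for CdCl with Di, 4 for Aa and 1 for Nnm with Kbr. In that test this list held for Ota and CdCl with Di (adjusted p = 0.0149 and 0.000225). It was lost for the others in the order given, at 0.424, 0.459, 0.13 and 0.471. TXNIP fell by 4.55, 5.99, 4.95, 6.35, 2.84 and 3.35 in that order of families. Ra 48 h and both Ota doses at 72 h ran the opposite way in the ATF4 and replication lists and share these later controls.

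Between the earlier and later control cultures limma called 1461 genes for CsA, 139 for Aa, 66 for Nnm with Kbr, 3213 for Ota, 1740 for Fk with Ra and 5405 for CdCl with Di. With the replicate block these were 3146 for CsA, 1555 for Aa and 852 for Nnm with Kbr. For CsA the count was 619, 824 and 676 without the 12 h controls 1, 2 and 3, and 583 without 48 h control 2. For Aa it was 61, 38 and 16 without the 24 h controls 1, 2 and 3, and 10, 17 and 453 without those of 48 h. For Nnm with Kbr it was 11, 28 and 2 without the 24 h controls and 3, 2 and 103 without those of 48 h. For Fk with Ra it was 951, 859 and 708 without the 12 h controls 1, 2 and 3, and 613 and 719 without the 48 h controls 1 and 2.

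Very long genes were lower with Aa at both doses and times. Of 71 such genes tested, 62 fell and 2 rose in Aa high 24 h, 67 and 2 in Aa high 48 h, 27 and 2 in Aa low 24 h, and 54 and 1 in Aa low 48 h. The first hypothesis, on Aa high with Ota high, failed. The list's median in Ota high 24 h lay at percentile 82.7 of random lists matched on level. It lay at 74.7 after quantile normalization, which decided nothing. For that joint pattern RNA degradation stayed open, as 0 comparisons with a low median had an ACTB difference under 1 control SD. With Aa alone the highest of the 4 medians was −0.97, below all 10000 random lists. At the high dose RNA degradation is argued against, as the median in each array lay at −2.34 or lower, while in the 1 other comparison with as large an ACTB difference, Ota high 72 h, the lowest was −0.993. At the low dose it stays open. ACTB lay above the control with the same number in all pairs, and the highest array median was −0.378. Against it, replicates 1 and 3, with ACTB below the control mean, gave −1.2 and −1.21 at 24 h. At 48 h they gave −1.54 and −1.86. Normalization is argued against by a highest median of −0.942 after quantile normalization. At the high dose less RNA made from very long genes may explain the pattern, as a hypothesis found and tested on the same data.

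The Nnm arrays numbered 2 lay nearer to the controls than replicates 1 and 3. The slope of their changes, each from the control with the same number, on the mean of the other pair was 0.224 in Nnm high 24 h, 0.372 in Nnm low 24 h, 0.289 in Nnm high 48 h and 0.42 in Nnm low 48 h. In upper quartile and ACTB difference 0 of the 4 arrays lay outside the range of the other 26. Nnm high 24 h at 0.981 and Nnm high 48 h at 0.984 lay below the others' lowest of 0.989 in correlation with their group. The pattern itself entails this, so that array quality stays open. A day or culture shared by all arrays with number 2 is argued against, as the lowest slope over the Kbr groups was 0.95. Mislabelled control arrays are argued against, as the lowest correlation of these changes with that mean was 0.624 across genes, and 5 control arrays put in the place of each gave at most 0.339. Their signs matched in at least 78.4% of genes, against at most 67.5%. A test of the slope itself, made earlier, had decided nothing. A weaker treatment of these cultures, or a mixture with control material, was not tested.

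Replicate 2 of Ra 48 h lay far from the other arrays of its control family. A mislabelled array is argued against, as its own group ranked 1 of 38 groups by correlation with it, at r = 0.971 across genes against 0.962 for Ra 12 h. Array quality stayed open. Without it 608 genes were called against 1016 with it, and the test had set beforehand that less than a rise by 1.5 times would speak against array quality. That bound was wrong, because leaving out any array leaves a group of 2 and the count was as unstable elsewhere, at 67 and 25 without control replicates 1 and 2 and 1542 without this array and Fk 12 h array 3, and because its upper quartile of 6.09 was the lowest of all arrays.

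For comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05, and the values are the genes called in the real split and the highest of the others. In most only 1 of the 10 splits, the real one, gave as many genes. These were Aa high 24 h (5546 and 0), Aa low 24 h (2576 and 0), Aa high 48 h (7139 and 0), Aa low 48 h (4111 and 3), the Aa doses (4971 and 2), Kbr high 24 h (2380 and 0), Kbr low 24 h (150 and 1), Kbr high 48 h (5643 and 1), Kbr low 48 h (3248 and 0) and the Kbr doses (886 and 45). The same held for Nnm low 24 h (2044 and 0), Nnm high 48 h (3053 and 14), Nnm low 48 h (1558 and 2) and Nnm against Kbr (6255 and 2). It held for Ota high 24 h (7236 and 2), Ota low 24 h (1527 and 1), Ota high 72 h (7044 and 0), Ota low 72 h (1785 and 2) and the Ota doses (6441 and 0). It also held for Fk 12 h (1 and 0), Ra 12 h (4 and 0), Ra 48 h (1016 and 3), Fk against Ra (805 and 3), CdCl 12 h (5383 and 1), CdCl 48 h (5130 and 1), Di 12 h (1308 and 3), Di 48 h (5231 and 0) and CdCl against Di (4703 and 3).

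In the control cultures between times, 1 of the 10 splits again gave as many genes in each family, with 1461 and 0 for CsA, 139 and 2 for Aa, 66 and 0 for Nnm with Kbr, 3213 and 0 for Ota, 1740 and 0 for Fk with Ra, and 5405 and 0 for CdCl with Di. In CsA 48 h 5 splits gave as many as the real one, with 1 and 5 genes. All 10 splits did so in CsA 12 h (0 and 0), Fk 48 h (0 and 77) and between the Nnm doses (0 and 1580). In Nnm high 24 h, with 3967 genes, the highest other split gave 1509, and it set Nnm replicate 2 beside control replicates 1 and 2. Between the Nnm doses the split with 1580 genes set replicates 1 and 3 of the high dose and replicate 1 of the low dose apart from the rest. Both point to the structure of the samples described for Nnm replicate 2. In CsA, Aa and Nnm with Kbr, where the numbers pair the samples, 4 of the 10 splits part all 3 pairs. Among these the highest other split gave 873 genes in Nnm high 24 h, 2 between the Aa doses, 1 in Nnm high 48 h and 1 between the Nnm doses, and limma called 0 in the other comparisons of these families. The splits with 1580, 45 and 5 genes part 1 pair, so that 2 replicate numbers lie whole on 1 side each.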
